A study of Mus musculus with 4 samples.

How the data were processed

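RNA from Pdgfra-positive lung fibroblasts of wild-type C57BL6 mice was profiled at E16.5, E18.5, P7 and P28, with 1 library per age. Per the labels, RNA was extracted with the QIAamp Circulating Nucleic Acid Kit, cDNA was made with the Verso cDNA kit, and libraries were made with Nextera XT and read as paired ends. The submitters' processing notes name TopHat and TopHat2 2.0.9, and the genome builds GRCm38 and mm10. The program that made the expression values is not given in the sources used here. The deposited table gives FPKM, scaled by the authors, for 23931 entries in 4 columns, 1 per age. Positive values go down to a log10 of -256, so they are model estimates and an exact 0 can be an estimate that was not made. Raw counts were not used here, and FPKM holds no read totals, so the depth per library is unknown. Relative depth was estimated from the most common ratio of values below 0.1 FPKM in both libraries of a pair, and it limits what can be said of rare transcripts.

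Entries that share a symbol were summed (258 symbols, 745 entries), which left 23444 symbols. Values were taken as log2(FPKM + 1). A gene was counted as higher or lower in a library when the difference was at least 1 (2-fold) and the higher library was at 5 FPKM or more. With 1 library per age no test was run and no p-value is given. Successive ages and the ends of the course were compared, and P7 against E16.5 was added after seeing the data. Genes at 5 FPKM or more in at least 1 library and at least 2-fold apart between their highest and lowest library were classed by the order of the 4 ages.

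Gene groups came from 44 lists with 914 gene entries, of which 912 were in the table. The mitochondrial genome list was empty, as no such genes were in the table. Members at 1 FPKM or more in at least 1 library were used. The median log2 difference of a list was set against 10000 random lists of the same size, matched on mean expression in 20 bins with a fixed seed, and its relative median is the difference from the median of those random lists. Percentiles describe these libraries only. Lists share some genes, so their medians are not independent. Mfap4 is on the general fibroblast, Col13a1 and elastic fibre lists, and Dcn on the general fibroblast, Col14a1 and proteoglycan lists. Etv5 is the 1 gene on both the FGF and the alveolar type 2 lists.

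Genes named in the text follow a fixed rule: Pdgfra, the 12 largest positive and 12 largest negative differences per comparison among genes at 10 FPKM or more in the higher library, up to 4 members per list with the largest difference, the most abundant member of each list, and the 3 most abundant members of lists for other cell types. Predicted or unnamed genes and small RNAs were passed over in the ranking. The genes with the highest FPKM per library, and the Y-linked genes, are given outside this rule. A result withheld for evaluation was left out. The comparisons, lists, thresholds, naming rule and scaling alternatives were fixed before the data were examined.

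The alternatives were pseudocounts of 0.1 and 5, no minimum, a minimum of 20 FPKM, a 4-fold threshold, median-ratio scaling (factors 1.15, 0.581, 1.38 and 1.08 in order of age), upper-quartile scaling, and a total without mitochondrial, erythroid and ribosomal protein genes. List medians under the alternatives used 2000 random lists each. Chosen after seeing the data were the removal of small RNA genes, of symbols with several entries and of genes on lists for other cell types. Transcript lengths for the sums of FPKM times length were median lengths from GENCODE M21, found for 21351 genes with small RNA genes left out, and coordinates are those of GENCODE M21 on GRCm38. The code was tested on simulated data of 12561 genes with 200 genes made 4-fold different. At equal scale 100% were recovered in each direction. With a library at 0.5 of its scale, 54% of higher and 100% of lower genes were recovered with 1582 false lower calls. Median-ratio scaling gave 100% and 0 false calls. The simulated noise was small, and changes were equal in number in both directions and made in abundant genes only. These rates therefore do not carry over to the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.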

Results

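The data are RNA-seq profiles of lung fibroblasts sorted for Pdgfra, the alpha receptor for platelet-derived growth factor, from wild-type C57BL6 mice. The series follows these cells over lung development, and the question addressed here is which transcripts differ between ages. There were 4 groups of 1 library each: embryonic day 16.5 (E16.5), embryonic day 18.5 (E18.5), postnatal day 7 (P7) and postnatal day 28 (P28). With 1 library per age no spread between animals can be given, so every difference below is a difference between libraries, described by its size and not tested. Values are the deposited FPKM, and 23444 gene symbols were listed, of which 12561 reached 1 FPKM in at least 1 library. FPKM keeps no read totals, so the depth of each library is unknown. Steps between low values put the depth of the E16.5 library at about 1.38 times that of E18.5, 0.949 times that of P7 and 1.05 times that of P28. The number of genes listed at 0 was 6520 at E16.5, 6210 at E18.5, 6580 at P7 and 6111 at P28.

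Pdgfra itself (GRCm38 chromosome 5, 75152292 to 75198215, plus strand) was abundant in every library, at 88.7, 95.9, 113 and 188 FPKM in order of age. The general fibroblast genes were led by Mfap4, a microfibril-associated glycoprotein, at 680.1 FPKM at E16.5, 825 at E18.5, 1231 at P7 and 4400 at P28 (higher at E18.5 than at P7 after scaling), and Col3a1, a fibrillar collagen chain, ranged from 187 at E18.5 to 1034 at P28. The gene with the highest FPKM was Gm20594 at E16.5 (2255), Lars2 at E18.5 (2568), Sparc at P7 (1639) and the club cell secretoglobin Scgb1a1 at P28 (19258). Across 12561 genes, Pearson's r of log2(FPKM + 1) was 0.851 between E16.5 and E18.5 and 0.673 between E16.5 and P28, where genes are not independent replicates.

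The E18.5 library stood apart in scale. Among the 7930 genes at 1 FPKM or more in all 4 libraries, 92.9% were lower at E18.5 than in the mean of the other 3 libraries, with a median log2 difference of -1.05. The median log2 ratio over these genes was -0.95 for E18.5 against E16.5, 1.25 for P7 against E18.5, -0.36 for P28 against P7 and -0.10 for P28 against E16.5. Gene groups are therefore described by a relative median, the median log2 difference of the list minus that of 10000 random lists matched on expression, and counts of genes are given for FPKM as deposited and after median-ratio scaling. A list is described as outside the random range where its percentile lay below 2.5 or above 97.5.

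**Figure D1:**
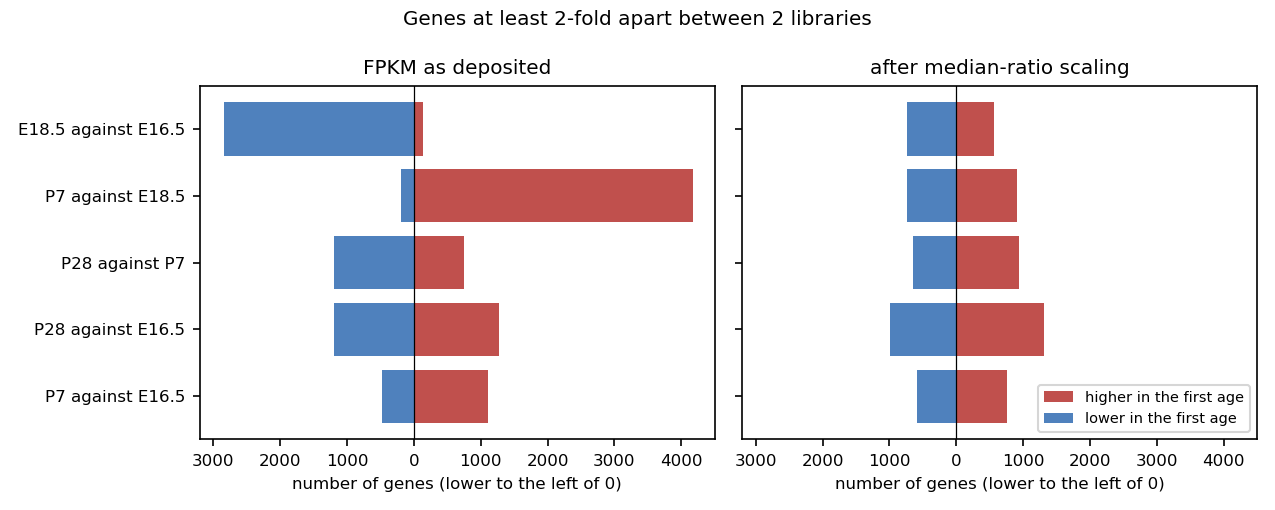
Number of genes at least 2-fold higher (red) or lower (blue) in the first-named library of each pair, on the deposited FPKM (left) and after median-ratio scaling (right), with the higher library at 5 FPKM or more. At E18.5 against E16.5 the 139 higher and 2837 lower genes became 564 and 734 after scaling.

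Of 6361 genes at least 2-fold apart between their highest and lowest library, 226 were higher at each successive age and 181 were lower at each successive age (343 and 245 of 3926 genes after scaling). The lowest value fell at E18.5 for 4672 genes as deposited and for 975 after scaling. The highest value fell at P28 for 1651 genes, or 1379 after scaling. C7, a component of the membrane attack complex, was higher at each successive age, at 0.0426 FPKM at E16.5, 0.770 at E18.5, 15.7 at P7 and 496 at P28. So was Inmt, an amine N-methyltransferase, at 0.169 FPKM at E16.5, 1.06 at E18.5, 2.27 at P7 and 1272 at P28. The imprinted gene H19 (GRCm38 chromosome 7, 142575529 to 142578143, minus strand) was lower at each successive age, at 309 FPKM at E16.5, 272 at E18.5, 18.7 at P7 and 0.158 at P28. Its neighbour Igf2, which encodes insulin-like growth factor 2 (GRCm38 chromosome 7, 142650766 to 142666816, minus strand), was at 99.8 FPKM at E16.5, 85.2 at E18.5, 16.1 at P7 and 4.17 at P28. After median-ratio scaling the E18.5 values of H19 and Igf2 lay above those of E16.5, with log2 differences of 0.79 and 0.75. The E18.5 value of Inmt likewise lay above that of P7 after scaling, a log2 difference of -0.10 for P7 against E18.5.

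**Figure D2:**
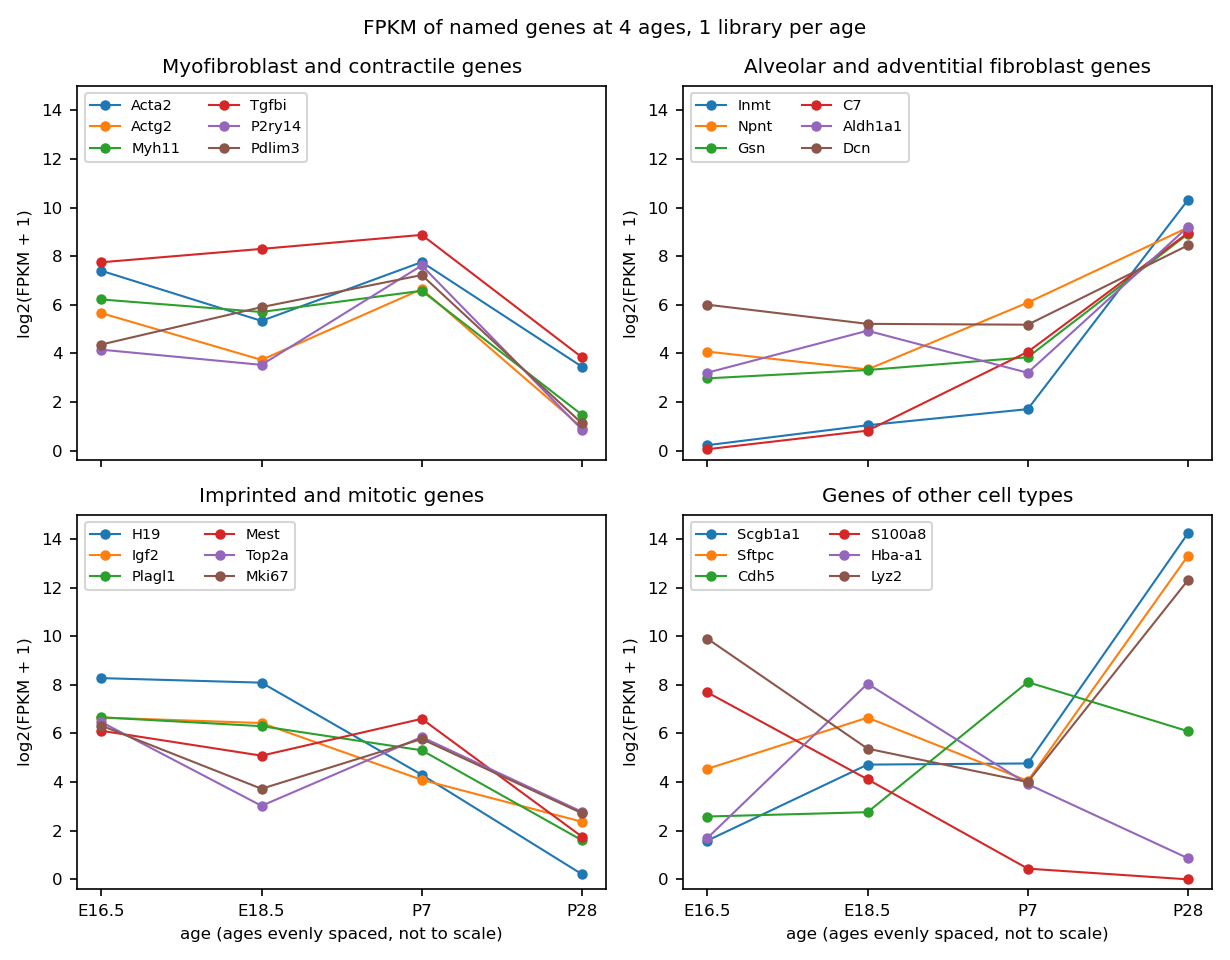
Log2(FPKM + 1) of named genes in the 4 libraries, 1 point per library, with lines joining the points of a gene and ages evenly spaced. Tgfbi stood at 214, 314, 469 and 13.3 FPKM in order of age, and Inmt reached 1272 FPKM at P28; the E18.5 points are on the lower scale of that library, and after scaling Tgfbi lies higher at E18.5 than at P7.

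E18.5 was compared with E16.5 to describe the last days before birth. Genes of cell division were lower at E18.5, while the medians of the alveolar myofibroblast, elastic fibre and glucocorticoid response lists stood above the shift of the library. This was not particular to them. Many other lists also stood above the random range, among them basement membrane (0.83), Col13a1 fibroblast (0.82), matrix protease and inhibitor (0.81) and complement (0.76). Others, such as glycolysis (-0.63), stood below it. Of 30 measured mitosis genes 29 were at least 2-fold lower (28 after scaling), with a relative median of -2.02, or 4.06-fold lower (percentile 0). The DNA topoisomerase Top2a was at 87.7 FPKM at E16.5 and 7.14 at E18.5, the spindle motor Kif11 at 28.6 and 1.53, and cyclin B1 (Ccnb1) at 21.0 and 0.769. Enpp2, which encodes autotaxin, was at 11.7 and 235 FPKM, a log2 difference of 4.22.

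The DNA replication list had a relative median of -1.49, with 27 of 34 genes at least 2-fold lower (24 after scaling). The ribonucleotide reductase subunit Rrm2 was at 37.2 FPKM at E16.5 and 1.21 at E18.5, Gins2 of the replicative helicase at 48.8 and 1.51, and Uhrf1 at 16.4 and 0.710. Hist1h2bl showed the lowest log2 difference among genes covered by the naming rule, -4.87, although histone genes are near-identical copies and their reads are uncertain. Among 15 fetal RNA-binding and chromatin genes (relative median -0.53), Stmn1 was at 122 FPKM at E16.5 and 16.9 at E18.5 and Ezh2 at 35.4 and 7.21. Glycolysis genes had a relative median of -0.63, and 9 of 20 were at least 2-fold lower (7 after scaling); with a pseudocount of 5 the median was -0.20, inside the random range. Gapdh was at 357 FPKM at E16.5 and 65.1 at E18.5, Pgk1 at 60.0 and 9.97, and Pgam1 at 104 and 16.4, genes whose processed copies in the genome make their reads less certain.

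The alveolar myofibroblast list had a relative median of 1.23, with 3 of 15 genes at least 2-fold higher and 3 lower as deposited (9 and 1 after scaling). Stc1 was at 2.91 FPKM at E16.5 and 29.5 at E18.5 and Pdlim3 at 19.6 and 58.9, while Cdh11 was at 165 and 41.1. Elastic fibre genes had a relative median of 0.64, with 2 of 22 at least 2-fold higher and 3 lower as deposited (7 and 1 after scaling). Elastin itself (Eln, GRCm38 chromosome 5, 134702593 to 134747323, minus strand) was at 69.9 FPKM at E16.5 and 472 at E18.5. The latent TGF-beta binding protein Ltbp2 was at 14.4 and 41.7, while Emilin2 and Emilin1 had log2 differences of -2.43 and -1.33 (-1.74 and -0.46 after median-ratio scaling). Contractile genes did not leave the random range (relative median -0.10), with Acta2, smooth muscle actin, at 168 FPKM at E16.5 and 39.5 at E18.5. Basement membrane genes had a relative median of 0.83, with 1 of 24 at least 2-fold higher as deposited (Col15a1, 1.96 FPKM at E16.5 and 8.24 at E18.5) and 1 lower (Nid2, 19.2 and 5.52), against 7 and 0 after scaling.

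The glucocorticoid response list had a relative median of 1.41, or 2.65-fold higher, with 9 of 14 genes at least 2-fold higher after scaling and 5 as deposited. The immediate early and dissociation list, a sign of sample handling, stood in the same direction at 0.62, with 6 of 23 genes higher after scaling, and 0 higher and 3 lower as deposited. The transcription factor Klf9 was at 3.69 FPKM at E16.5 and 37.2 at E18.5, and the metallothioneins Mt1 and Mt2 were at 9.87 and 2.43 at E16.5 and 60.9 and 14.9 at E18.5. Other genes among the 12 with the largest positive differences were angiotensinogen (Agt), at 1.42 FPKM at E16.5 and 32.9 at E18.5, Ccdc3, at 4.01 and 69.3, the flavin monooxygenase Fmo2, at 12.7 and 144, and the cytochrome Cyp2e1, at 0.298 and 16.0. Rpl34 was at 7.07 and 97.5, and ribosomal protein genes have many processed copies, so its reads are uncertain.

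Markers of other cell types differed beside these groups. Relative medians were also outside the random range, and higher, for mesothelium (1.85), alveolar type 1 epithelium (1.46), airway epithelium (1.28), endothelium (1.21), pericytes (1.12), alveolar type 2 epithelium (1.08) and lymphatic endothelium (1.00). As deposited, 0 of 15 endothelial genes were at least 2-fold higher (4 after scaling), 2 of 12 pericyte (4) and 2 of 9 mesothelium genes (2). So were 1 of 11 alveolar type 1 (3), 1 of 10 airway (1) and 0 of 4 lymphatic endothelial genes (0). Of 15 alveolar type 2 genes 2 were higher and 2 lower (3 and 0 after scaling). Most genes of these lists were thus not 2-fold higher under either setting. Random lists were matched on the mean of all 4 libraries. The leukocyte list had a relative median of -2.71, with 15 of 16 genes at least 2-fold lower at E18.5, and it held 1.00% of summed FPKM at E16.5 and 0.105% at E18.5. Lysozyme (Lyz2) was at 955 FPKM at E16.5 and 40.5 at E18.5, S100a8 at 206 and 16.3, and cathepsin S (Ctss) at 167 and 5.98. Granzyme A (Gzma) was at 21.9 at E16.5 and listed at 0 at E18.5. Coro1a, Alox5ap, Ly86, Ifitm6, Stfa3 and the mast cell protease Cpa3 were also among the 12 genes with the largest negative differences. The erythroid list had a relative median of 5.70, with Hba-a1 at 2.24 FPKM at E16.5 and 264 at E18.5 and Hbb-bt at 2.46 and 162; globin genes are near-identical copies, so the split between them is uncertain. As deposited, 139 genes were at least 2-fold higher and 2837 at least 2-fold lower, and median-ratio scaling gave 564 and 734, so the split of single genes near 2-fold rests on the scale of the E18.5 library.

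P7 was compared with E18.5 to describe the span from before birth into the formation of alveoli. Genes of mitosis and of endothelial cells were higher at P7, and ribosomal protein, glucocorticoid response, immediate early and globin genes were lower relative to the shift of 1.25. Of 30 mitosis genes 27 were at least 2-fold higher (23 after scaling), with a relative median of 1.31 (percentile 100); cyclin A2 (Ccna2) was at 2.19 FPKM at E18.5 and 28.0 at P7 and Aurkb at 1.24 and 18.3. H19 was at 272 FPKM at E18.5 and 18.7 at P7 and Igf2 at 85.2 and 16.1. P2ry14, a receptor for nucleotide sugars on the alveolar myofibroblast list, was at 10.6 FPKM at E18.5 and 195 at P7.

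The glucocorticoid response list had a relative median of -1.78, or 3.44-fold lower, with 11 of 14 genes at least 2-fold lower after scaling and 6 as deposited. Mt1 was at 60.9 FPKM at E18.5 and 0.271 at P7 and Zbtb16 at 7.91 and 0.317, while the kinase Sgk1 on the same list was at 4.33 and 77.0. The immediate early list, which tissue dissociation can also raise, had a relative median of -2.04, with Zfp36 at 564 FPKM at E18.5 and 61.2 at P7, Atf3 at 46.3 and 4.87, and Klf4 at 7.72 and 76.0. The ribosomal protein list had a relative median of -1.28, with 65 of 81 genes at least 2-fold lower after scaling and 6 as deposited. Its share of summed FPKM was 14.5% at E18.5 and 6.93% at P7. Imprinted growth genes had a relative median of -0.62, with 4 of 16 at least 2-fold higher and 4 lower as deposited (0 and 7 after scaling). Meg3 was at 14.3 FPKM at E18.5 and 1.93 at P7.

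Among the fibroblast groups, contractile genes stayed inside the random range at 0.38, with 10 of 16 at least 2-fold higher as deposited and 3 after scaling. Acta2 (GRCm38 chromosome 19, 34241090 to 34255590, minus strand) was at 39.5 FPKM at E18.5 and 216 at P7, Actg2 at 12.3 and 99.1, and Cald1 at 39.8 and 249.7. On the alveolar myofibroblast list (relative median 0.19, inside the random range), Igfbp5 was at 9.84 FPKM at E18.5 and 142 at P7, Enpp2 differed by a log2 difference of -3.56, and the hedgehog-binding protein Hhip was at 52.4 and 8.09. Of the elastic fibre genes, Fbln2 was at 0.941 FPKM at E18.5 and 34.9 at P7, and lysyl oxidase (Lox) at 78.0 and 15.7. Foxf1, a transcription factor on the general fibroblast list, was at 17.4 FPKM at E18.5 and 126 at P7. All 15 endothelial genes were also higher at P7, so the source cells of single genes here cannot be told from these values. Lipofibroblast genes had a relative median of -0.94, a value that came inside the random range after median-ratio scaling, with Apoe at 36.4 FPKM at E18.5 and 11.4 at P7. MHC class I presentation genes had a relative median of 0.75 (0.28 and inside the random range with a pseudocount of 5), with H2-K1 at 2.21 FPKM at E18.5 and 45.3 at P7 and H2-D1 at 2.14 and 48.3. The scavenger receptor Scara5 was at 24.0 FPKM at E18.5 and 0.457 at P7.

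All 15 endothelial genes were at least 2-fold higher at P7, as deposited and after scaling, with a relative median of 2.90, or 7.46-fold higher. Their sum was 0.0533% of FPKM at E18.5 and 0.697% at P7. Vascular endothelial cadherin (Cdh5) was at 5.79 FPKM at E18.5 and 276 at P7 and Calcrl at 5.63 and 272. Tmem100, at 0.199 FPKM at E18.5 and 120.3 at P7, Epas1, at 1.84 and 180.4, Cd93, at 4.37 and 199, and Hpgd, at 1.54 and 243, were among the 12 genes with the largest positive differences, with Glp1r, Pcdh1, Slc9a3r2, Ly6a and Tspan13. Xist, the RNA that coats the inactive X chromosome (GRCm38 chromosome X, 103460366 to 103483254, minus strand), was at 0.0157 FPKM at E18.5 and 87.3 at P7. Erythroid genes had a relative median of -5.04, with Hba-x at 81.8 at E18.5 and listed at 0 at P7. The leukocyte list had one of -2.18, with 5 of 16 genes lower (7 after scaling) and 1 higher. The alveolar type 2 list had one of -1.73, with 2 of 15 genes lower and 1 higher (4 and 0 after scaling). The airway list had one of -1.13, with 0 of 10 genes lower and 1 higher (1 and 1 after scaling). Most genes of these 2 epithelial lists were thus not 2-fold apart, and their medians mainly stood below the shift of the library. Actr3 and Wwtr1, at 27.8 and 14.2 at E18.5, were also listed at 0 at P7; Actr3 encodes a subunit of the Arp2/3 complex that cells use widely, so an exact 0 in this table can be an estimate that was not made. As deposited, 4180 genes were at least 2-fold higher and 191 lower, against 904 and 738 after median-ratio scaling, and Pdgfra itself was higher at P7 as deposited (log2 difference 0.23) but lower after each scaling (-1.003 with median-ratio scaling).

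P7 was also set against E16.5, a comparison added after the scale of the E18.5 library was seen. The medians of the alveolar myofibroblast and elastic fibre lists were higher at P7 relative to random lists, and that of the glycolysis list was lower. The alveolar myofibroblast list had a relative median of 0.94, with 8 of 15 genes at least 2-fold higher and 1 lower; among the higher were Stc1, at 2.91 FPKM at E16.5 and 31.0 at P7, and Aspn, at 3.16 and 30.0. Elastic fibre genes had a relative median of 0.68, with 10 of 22 at least 2-fold higher and 3 lower. Eln was at 69.9 FPKM at E16.5 and 501 at P7 and Ltbp2 at 14.4 and 122, while Emilin2 had the largest difference of the list, -3.50. Glycolysis genes had a relative median of -1.26, with 8 of 20 at least 2-fold lower and 0 higher, and the glucose transporter Slc2a1 at 22.7 FPKM at E16.5 and 2.85 at P7. Mitosis genes had a relative median of -0.64, and 1 of 30 was at least 2-fold lower. The immediate early and dissociation list stood at -1.57, further from random lists than the glycolysis list, with 13 of 23 genes lower and 2 higher. Of the other cell types, the endothelial list stood at 4.22, mesothelium at 2.40, pericytes at 1.35 and leukocytes at -4.71. In all, 1110 genes were at least 2-fold higher and 471 lower, against 756 and 593 after scaling.

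P28 was compared with P7 to describe the end of alveolar formation. Most contractile and alveolar myofibroblast genes were lower at P28, and most complement, Col13a1 fibroblast and lipofibroblast genes were higher. Of 16 contractile genes 13 were at least 2-fold lower (11 after scaling), with a relative median of -1.89, or 3.71-fold lower (percentile 0). Acta2 was at 216 FPKM at P7 and 9.95 at P28, Actg2 at 99.1 and 0.931, and smooth muscle myosin (Myh11) at 94.5 and 1.78. Inmt (GRCm38 chromosome 6, 55170626 to 55175043, minus strand) was at 2.27 FPKM at P7 and 1272 at P28, a log2 difference of 8.60.

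On the alveolar myofibroblast list 10 of 15 genes were at least 2-fold lower and none was higher, with a relative median of -2.14. Tgfbi (GRCm38 chromosome 13, 56609523 to 56639562, plus strand) was at 469 FPKM at P7 and 13.3 at P28, P2ry14 at 195 and 0.823, and Pdlim3 at 148 and 1.18. Ltbp2 was at 122 FPKM at P7 and 5.90 at P28 and the fibrillin Fbn2 at 14.0 and 0.436, within an elastic fibre list that did not leave the random range (0.22). The prolyl hydroxylase subunit P4ha3 was at 122 FPKM at P7 and 2.37 at P28, Egfem1 at 156 and 0.0693, and the protease-like Prss35 at 104 and 0.768. Agt, at 46.0 FPKM at P7 and 0.776 at P28, and Ccdc3, at 59.0 and 1.35, completed the 12 largest negative differences with Mest and Xist. Wnt genes stayed inside the random range (-0.22), with Lef1 at 11.7 FPKM at P7 and 0.0605 at P28 and Wnt5a at 47.1 and 5.20. Fgf18 was at 55.7 FPKM at P7 and 4.10 at P28. Hox genes had a relative median of -1.03, with Hoxb5 at 45.4 FPKM at P7 and 7.98 at P28.

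The Col13a1 alveolar fibroblast list had a relative median of 2.53, or 5.77-fold higher, with 11 of 14 genes at least 2-fold higher (13 after scaling) and 1 lower. Integrin alpha 8 (Itga8) was at 11.4 FPKM at P7 and 128 at P28, Ces1d at 7.89 and 89.9, and Cxcl14 at 0.743 and 28.7. The Col14a1 adventitial list had a relative median of 1.26, with 7 of 15 genes higher and 2 lower (11 and 2 after scaling). Gelsolin (Gsn) was at 13.3 FPKM at P7 and 482 at P28, Pi16 at 0.496 and 27.3, and decorin (Dcn) at 35.3 and 348. Lipofibroblast genes had a relative median of 1.34, and 10 of 17 were at least 2-fold higher. The retinol acyltransferase Lrat was at 0.0832 FPKM at P7 and 15.3 at P28 and Apoe at 11.4 and 145. Retinoid genes had a relative median of 1.19, with 6 of 12 higher and 2 lower, and the retinaldehyde dehydrogenase Aldh1a1 was at 8.21 FPKM at P7 and 589 at P28. Tcf21, a fibroblast transcription factor, was at 25.9 FPKM at P7 and 141 at P28.

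Of 14 complement genes 12 were at least 2-fold higher at P28, with a relative median of 2.94. C7 was at 15.7 FPKM at P7 and 496 at P28 and the C1 inhibitor Serping1 at 84.3 and 610.5. The glucocorticoid response list had a relative median of 2.29, with Hsd11b1, which reactivates glucocorticoids, at 8.51 FPKM at P7 and 250.4 at P28. The immediate early and dissociation list stood in the same direction at 0.98, with 8 of 23 genes higher and 2 lower. Mitosis genes had a relative median of -2.29, with 27 of 30 at least 2-fold lower, and DNA replication genes one of -1.37. Aurkb was at 18.3 FPKM at P7 and 1.10 at P28 and Rrm2 at 31.4 and 2.15. Imprinted growth genes had a relative median of -0.88, with Mest at 96.2 FPKM at P7 and 2.38 at P28 and Plagl1 at 38.6 and 2.05.

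Epithelial markers were higher beside these groups. The values do not tell which cells a transcript of the retinoid, complement or other lists came from. All 15 alveolar type 2 genes were at least 2-fold higher at P28, with a relative median of 5.95, and 7 of 10 airway genes were, with a relative median of 5.10. These lists held 5.96% and 9.08% of summed FPKM at P28, against 0.0191% and 0.0323% at P7. Surfactant protein C (Sftpc) was at 15.5 FPKM at P7 and 10149 at P28, Scgb1a1 at 26.2 and 19258, Sftpb at 1.81 and 723, and Sftpa1 at 1.02 and 689.7. Slc34a2, Cyp2f2, Cxcl15, Chil1, Cbr2 and Lyz2 were also among the 12 largest positive differences, and Scgb3a1 was at 258 at P28 and listed at 0 at P7. Mesothelium genes had a relative median of 1.68, with 5 of 9 higher, and alveolar type 1 genes one of 1.30, with 5 of 11 higher. The endothelial list had a relative median of -1.54 and the pericyte list one of -1.73, with Postn at 205 FPKM at P7 and 10.5 at P28. As deposited, 747 genes were at least 2-fold higher and 1202 lower, and median-ratio scaling gave 932 and 654. With genes of the other cell type lists left out, an alternative chosen after seeing the data, 712 genes were higher and 1176 lower. Only listed markers were left out, so other genes of those cell types remain in these counts.

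P28 was compared with E16.5 to set the ends of the course side by side. Most complement, Col14a1 and Col13a1 fibroblast genes were higher at P28, and most imprinted growth, mitosis and leukocyte genes were lower. Complement genes had a relative median of 3.89, or 14.8-fold higher, with 13 of 14 at least 2-fold higher. C7 was at 0.0426 FPKM at E16.5 and 496 at P28, C1s at 0.619 and 98.1, and C3 at 18.2 and 450.2. Epithelial lists were also higher at P28, so the source cells of such transcripts cannot be told from these values. H19 was at 309 FPKM at E16.5 and 0.158 at P28, a log2 difference of -8.07, the lowest among genes the naming rule covers.

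Of 16 imprinted growth genes 12 were at least 2-fold lower and 1 higher, with a relative median of -2.29. Plagl1 was at 100.5 FPKM at E16.5 and 2.05 at P28, Mest at 68.1 and 2.38, and Igf2 at 99.8 and 4.17. Of 30 mitosis genes 29 were at least 2-fold lower (relative median -2.95, percentile 0), with Mki67 at 79.2 FPKM at E16.5 and 5.59 at P28 and Top2a at 87.7 and 5.86. DNA replication genes had a relative median of -2.24. Fetal RNA-binding and chromatin genes had one of -1.43, with Igf2bp3 at 14.5 FPKM at E16.5 and 0.804 at P28 and Sox11 at 11.2 and 1.07. Of 81 ribosomal protein genes 64 were at least 2-fold lower (60 after scaling), with a relative median of -0.98. Glycolysis genes had a relative median of -0.99, with Gapdh at 357 FPKM at E16.5 and 88.2 at P28. The immediate early and dissociation list stood at -0.66, with 9 of 23 genes lower and 4 higher.

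The Col14a1 adventitial list had a relative median of 3.32, with 11 of 15 genes at least 2-fold higher and 1 lower, and Gsn was at 6.86 FPKM at E16.5 and 482 at P28 and Dpt at 12.8 and 238. The Col13a1 list had one of 3.07, with 11 of 14 higher and 1 lower, and nephronectin (Npnt) at 15.9 FPKM at E16.5 and 579 at P28 and Limch1 at 5.99 and 164. Superoxide dismutase 3 (Sod3) was at 0.145 FPKM at E16.5 and 311 at P28. Contractile genes had a relative median of -1.61, with Myh11 at 73.5 FPKM at E16.5 and 1.78 at P28. Interferon response genes had one of 1.44, with Ifitm3 at 134 FPKM at E16.5 and 745 at P28 and Gbp2 at 0.949 and 14.9. MHC class I presentation genes had one of 1.16, with H2-K1 at 17.3 FPKM at E16.5 and 126 at P28. Basement membrane genes had one of 1.29. Matrix protease and inhibitor genes had one of 0.82, with the inhibitor Timp3 at 13.1 FPKM at E16.5 and 208 at P28 and Adamts15 at 1.33 and 48.4.

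The leukocyte list had a relative median of -4.26, with 12 of 16 genes at least 2-fold lower at P28 and 3 higher, among them Lyz2, at 955 FPKM at E16.5 and 5062 at P28, and Cd74, at 30.2 and 439. Fcer1g was at 165 FPKM at E16.5 and 1.19 at P28, Tyrobp at 78.8 and 0.554, and S100a9 at 128 and 0.838. The stefins Stfa1, Stfa2, Stfa2l1 and Stfa3, C1qb, Ctss and S100a8 were also among the 12 largest negative differences; stefin genes are close copies and their reads are uncertain. Alveolar type 2 genes had a relative median of 4.03, airway genes one of 5.03, endothelial genes one of 2.43, lymphatic endothelial genes one of 1.79, pericyte genes one of -0.64 and erythroid genes one of -0.86, which came inside the random range with a pseudocount of 5 (-0.28) and with the total without mitochondrial, erythroid and ribosomal genes (-0.64). In all, 1271 genes were at least 2-fold higher and 1194 lower, against 1311 and 997 after median-ratio scaling; rescaling to the total without erythroid and ribosomal genes gave 807 and 1853.

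**Figure D3:**
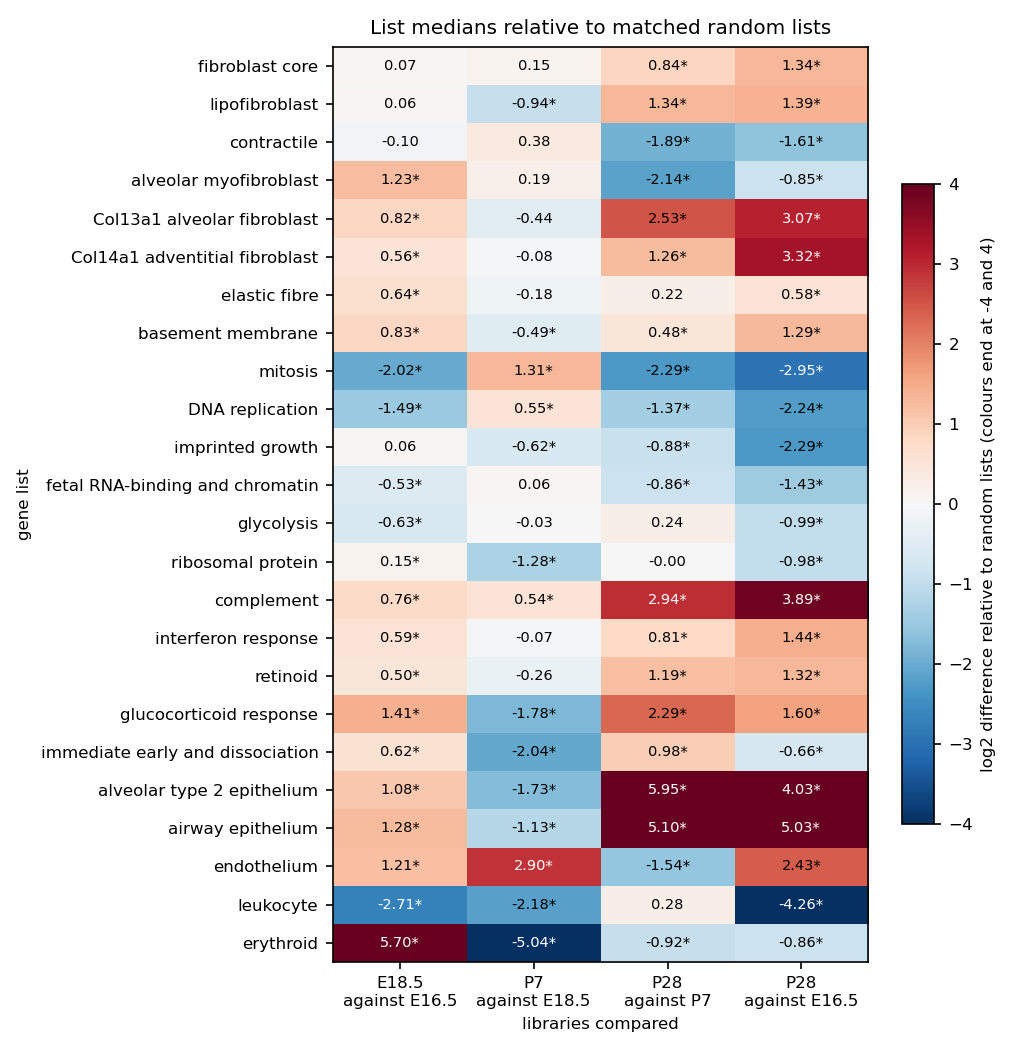
Relative medians of 24 gene lists (rows) in 4 comparisons of libraries (columns), in log2 units, red for higher and blue for lower in the first-named library, with an asterisk where the list lay outside the random range. The contractile list stood at -1.89 at P28 against P7, the complement list at 3.89 at P28 against E16.5, and the erythroid list at 5.70 at E18.5 against E16.5; no list outside the range turned its sign under the 3 scalings.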

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

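As deposited, E18.5 against E16.5 gave 139 higher and 2837 lower genes, and P7 against E18.5 gave 4180 and 191. Of 156 list medians outside the random range, none reversed and 22 came inside the range under at least 1 alternative. Lists inside the range were not rerun, and a minimum FPKM does not enter list medians. Of 217 gene differences, 13 changed class under at least 1 alternative. With 1 library per age no library could be left out. No paired analysis was possible because each age has 1 library and the labels tie no libraries together. Read depth is unknown, so low values of rare transcripts cannot be told from missing reads. The reduced total leaves out mitochondrial, erythroid and ribosomal protein genes, although the table held no mitochondrial genome genes. Why a value moved was not tested, apart from higher minimums and thresholds, which can only leave genes out.

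With a pseudocount of 5, the number of higher genes was 87 for E18.5 against E16.5, 2301 for P7 against E18.5 and 708 for P7 against E16.5, and the number of lower genes was 1329 for E18.5 against E16.5, 674 for P28 against P7 and 765 for P28 against E16.5. It gave 2736 genes lowest at E18.5. With no minimum FPKM, the number of higher genes was 210 for E18.5 against E16.5, 1202 for P28 against P7 and 1927 for P28 against E16.5, and the number of lower genes was 306 for P7 against E18.5 and 795 for P7 against E16.5. With a minimum of 20 FPKM, the number of higher genes was 60 for E18.5 against E16.5, 1437 for P7 against E18.5, 342 for P28 against P7, 551 for P28 against E16.5 and 520 for P7 against E16.5, and the number of lower genes was 882 for E18.5 against E16.5, 86 for P7 against E18.5, 530 for P28 against P7, 509 for P28 against E16.5 and 189 for P7 against E16.5. It gave 108 genes higher at each successive age, 90 genes lower at each successive age and 1599 genes lowest at E18.5. With median-ratio scaling, the number of higher genes was 564 for E18.5 against E16.5 and 904 for P7 against E18.5, and the number of lower genes was 734 for E18.5 against E16.5, 738 for P7 against E18.5 and 654 for P28 against P7. It gave 343 genes higher at each successive age and 975 genes lowest at E18.5. With upper-quartile scaling, the number of higher genes was 601 for E18.5 against E16.5, 766 for P7 against E18.5 and 683 for P7 against E16.5, and the number of lower genes was 729 for E18.5 against E16.5, 843 for P7 against E18.5 and 649 for P28 against P7. It gave 312 genes lower at each successive age and 835 genes lowest at E18.5. With the reduced total, the number of higher genes was 477 for E18.5 against E16.5, 1136 for P7 against E18.5 and 807 for P28 against E16.5, and the number of lower genes was 916 for E18.5 against E16.5, 626 for P7 against E18.5 and 1853 for P28 against E16.5. It gave 464 genes lower at each successive age and 902 genes lowest at E18.5. With a 4-fold threshold, the number of higher genes was 55 for E18.5 against E16.5, 1049 for P7 against E18.5, 348 for P28 against P7, 591 for P28 against E16.5 and 424 for P7 against E16.5, and the number of lower genes was 582 for E18.5 against E16.5, 93 for P7 against E18.5, 333 for P28 against P7, 474 for P28 against E16.5 and 246 for P7 against E16.5.

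List medians that kept their sign but came inside the random range follow. With a pseudocount of 0.1 they were for P7 against E18.5 fibrillar collagen and processing 0.24 and chondrocyte 1.25, and for P28 against E16.5 fibrillar collagen and processing 0.49, and for E18.5 against E16.5 retinoid 0.49, and for P7 against E16.5 Hox 0.49 and Schwann and neural 2.19. With a pseudocount of 5 they were for P7 against E16.5 basement membrane 0.17, MHC class I presentation 0.23, interferon response 0.11, alveolar type 1 epithelium 0.16 and erythroid 0.13, and for P28 against P7 hedgehog -0.15 and erythroid -0.15, and for E18.5 against E16.5 glycolysis -0.20 and ribosomal protein 0.11, and for P7 against E18.5 MHC class I presentation 0.28, complement 0.14 and replication-dependent histone 0.12, and for P28 against E16.5 erythroid -0.28. With median-ratio scaling they were for P7 against E18.5 lipofibroblast -0.29, fibrillar collagen and processing 0.20, basement membrane -0.31 and chondrocyte 0.66, and for P28 against E16.5 fibrillar collagen and processing 0.45, and for E18.5 against E16.5 retinoid 0.24. With upper-quartile scaling they were for P7 against E18.5 lipofibroblast -0.30, fibrillar collagen and processing 0.17, basement membrane -0.27, alveolar type 1 epithelium -0.48 and chondrocyte 0.65, and for E18.5 against E16.5 retinoid 0.24. With the reduced total they were for P7 against E18.5 fibrillar collagen and processing 0.21, alveolar type 1 epithelium -0.42 and chondrocyte 0.73, and for P28 against E16.5 fibrillar collagen and processing 0.40 and erythroid -0.64, and for P28 against P7 hedgehog -0.33, and for E18.5 against E16.5 retinoid 0.27.

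With median-ratio scaling the reversed log2 differences were H19 0.79 and Igf2 0.75 for E18.5 against E16.5, and Inmt -0.10, Mfap4 -0.67, Pdgfra -1.003 and Tgfbi -0.67 for P7 against E18.5. With upper-quartile scaling the reversed log2 differences were H19 0.81 and Igf2 0.77 for E18.5 against E16.5, and Inmt -0.17, Mfap4 -0.78, Pdgfra -1.11 and Tgfbi -0.77 for P7 against E18.5. With the reduced total the reversed log2 differences were H19 0.68 and Igf2 0.64 for E18.5 against E16.5, and Mfap4 -0.51, Pdgfra -0.85 and Tgfbi -0.51 for P7 against E18.5. Pdgfra at P28 against E16.5 was 0.64 with the reduced total, Cdh11 at E18.5 against E16.5 was -0.99 with upper-quartile scaling, and Col15a1 was 0.93 with a pseudocount of 5. Also at E18.5 against E16.5, Emilin1 was -0.93 with a pseudocount of 5 and -0.46, -0.44 and -0.57, and Nid2 -0.75, -0.73 and -0.86, with median-ratio scaling, upper-quartile scaling and the reduced total. Leaving out small RNA genes, symbols with several entries or genes of other cell type lists moved no count by more than 1.5 times. These 3 alternatives were chosen after seeing the data. They take out few genes (7 symbols with several entries reached 5 FPKM), so the counts had little room to move. Listed markers are only a part of the genes of a cell type, so their removal does not test RNA of other cells. P7 against E16.5 was also chosen after seeing the data.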

Other observations

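The 2 tests on summed FPKM times transcript length, the depth test at E18.5, the endothelial test and all values for P7 against E16.5 were chosen only after the result was seen.

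The circadian list had a relative median of 0.57 at E18.5 against E16.5, 0.68 at P28 against P7 and 0.78 at P28 against E16.5. At P28 against P7 2 of 14 genes were at least 2-fold higher and 2 lower, and the clock repressor Nr1d1 was at 0.448 FPKM at E16.5, 0.438 at E18.5, 6.64 at P7 and 98.8 at P28. TGF-beta and BMP genes had a relative median of 0.64 at P7 against E16.5, with the inhibitory Smad6 at 2.83 FPKM at E16.5 and 26.6 at P7, and stayed inside the random range at P28 against P7 (-0.23), where Bmp3 was at 9.82 FPKM at P7 and 112 at P28 and Tgfb2 at 42.2 and 7.06. FGF genes had a relative median of 0.65 at P28 against P7, with 7 of 19 at least 2-fold higher and 4 lower (8 and 4 after scaling), and Fgf7 at 9.48 FPKM at P7 and 38.2 at P28. Hedgehog genes had one of -0.43 (inside the random range at -0.15 with a pseudocount of 5 and at -0.33 with the reduced total), with the hedgehog receptor Ptch1 at 51.3 FPKM at P7 and 17.1 at P28 and Foxf2 at 60.2 and 13.7. Leucine-rich and large proteoglycan genes had a relative median of 0.77, with Prelp at 66.6 FPKM at P7 and 469 at P28 and the glypican Gpc4 at 45.6 and 3.68. Fibrillar collagen genes stayed inside the range at P28 against P7 (0.18), with the procollagen enhancer Pcolce2 at 15.3 FPKM at P7 and 280.0 at P28. Cholesterol synthesis genes had a relative median of 0.70, with Sc5d at 2.98 FPKM at P7 and 14.2 at P28. Oxidative phosphorylation genes stayed inside the range there (0.24), with Atp5b at 721 FPKM at P7 and 517 at P28. Replication-dependent histone genes had a relative median of -1.42, and their near-identical copies make single values uncertain.

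Markers of mesothelium were higher at P28 than at E16.5, with a relative median of 4.26 and mesothelin (Msln) at 0.0259 FPKM at E16.5 and 38.9 at P28. Alveolar type 1 genes had a relative median of 3.15, with Emp2 at 5.43 FPKM at E16.5 and 55.3 at P28. Lymphatic endothelial genes stood at 1.91 for P7 against E18.5, with Lyve1 at 5.23 FPKM at E18.5 and 146 at P7. Of the Schwann and neural and chondrocyte lists 2 and 3 genes were measured, and at P28 against E16.5 both lists stayed inside the random range, at 0.49 and -0.07.

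Transcripts of another cell type stood out in each library: most leukocyte genes at E16.5, erythroid genes at E18.5 (0.669% of summed FPKM, not tested further), endothelial genes at P7 and epithelial genes at P28. The leukocyte list held 1.00% of summed FPKM at E16.5 and 2.56% at P28, where Lyz2 (5062 FPKM) and Cd74 (439) carried it. At P28 12 of its 16 genes were at least 2-fold lower than at E16.5 and 3 were higher. The larger sum at P28 therefore does not stand for the list as a whole. The epithelial and leukocyte tests were written apart beforehand and joined with endothelium as 1 pattern once results were known. Leaving out epithelial and leukocyte genes whose values had been seen, 80.6% (25 of 31) of epithelial genes were at least 2-fold higher at P28 than at P7, and 100% (14 of 14) of leukocyte genes at E16.5 than at P7. The test of library scaling was all but fixed, because the factors (1.38 at P7, 1.08 at P28 and 1.15 at E16.5) raise both differences. After median-ratio scaling the median log2 difference was 3.44 for the epithelial and 4.08 for the leukocyte genes. Over 7930 genes the median log2 ratio was -0.36 for P28 against P7 and 0.23 for P7 against E16.5. These shifts lie opposite to the higher epithelial genes at P28 and leukocyte genes at E16.5, which argues against scaling. RNA of other cells may be the source at P28 and E16.5. Scgb1a1 and Sftpc were at 19258 and 10149 FPKM at P28, and Lyz2 and S100a8 at 955 and 206 at E16.5. A sort for Pdgfra would lower the number of such cells, but its purity is not known from these values. Expression by the fibroblasts of those ages stays open and untested. Endothelial RNA at P7 cannot be told apart from expression by the fibroblasts, because the share of 100% (15 of 15) higher than at E16.5 restates values already seen.

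Most genes had lower FPKM in the E18.5 library. Among listed genes, a few genes taking most of the reads is argued against. The 50 leading genes held a share of summed FPKM times length -5.41 percentage points from the highest other library. That share was 20.4% at E18.5, against 14.4% at E16.5, 14.2% at P7 and 25.8% at P28. Lars2 alone held 2.98% at E18.5, against 0.250% at E16.5, 0.123% at P7 and 0.425% at P28. Transcripts not listed, such as those of the mitochondrial genome, are not covered by this test. A first form of it, written beforehand, gave -0.0285 over 7930 genes. That form was void, because equal totals fix its outcome, and was replaced. Reads outside the gene models cannot be told apart as a cause: summed FPKM times length at E18.5 was 58.3% of the lowest other library, but lower FPKM of most genes all but fixes that value. Genomic DNA or unspliced RNA stays open too. The share of 1502 receptor genes above 0 was highest at E18.5, at 31.8% (exact binomial interval 29.5% to 34.2%). It was 27.9% (25.6% to 30.2%) at P28, 20.4% (18.4% to 22.5%) at P7 and 14.0% (12.3% to 15.9%) at E16.5. The E18.5 interval lay above those of P7 and E16.5 but overlapped that of P28, so the test could not decide. The same genes were scored in each library, so overlap of separate intervals does not show equal shares. E18.5 had the lowest estimated depth (E16.5 at 1.38 times E18.5, and E18.5 at 0.694 times P7 and 0.762 times P28). Lower depth by itself would not lower the FPKM of most genes, because FPKM already divides by depth. The program that made the FPKM is not given, so this division was not checked. The depth test could not decide, as the 6210 genes listed at 0 lie between 6111 and 6580 elsewhere. Age itself stays open because 1 library stands for each age.

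Xist was at 87.3 FPKM in the P7 library and at most 0.0534 in the others. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, picked for this test, summed to 25.6, 12.6 and 22.6 FPKM at E16.5, E18.5 and P28 and to 0 at P7, which is 0 percent of the lowest other library. A different sex makeup of the animals may be the cause, with a female source at P7 and a male source elsewhere. The labels used here give no sex, so age and sex cannot be separated in comparisons that include P7. An estimate not made, as for genes such as Actr3 listed at 0 at P7, was not tested for these 4 genes.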
